A study of Solanum lycopersicum with 20 samples.

How the data were processed

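Gene expression was measured in leaf and fruit pericarp of tomato (Solanum lycopersicum, cultivar Reiyo) on an Affymetrix tomato GeneChip, on which each transcript is read by a set of short probes laid toward its 3' end. The plants were grown in hydroponics at 450 to 500 PPF (photosynthetic photon flux) and 900 ppm CO2, with 16 h of light at 25 °C and 8 h of dark at 20 °C. After flowering, the second truss, the leaf beneath it and the apical meristem were kept and the other leaves and trusses were taken off. The kept leaf was then lit by LEDs at 200 or 1000 PPF. The unit written with these light levels in the labels, pmol per square metre per second, was not checked, so the levels serve here only as names of the groups. Leaves were harvested at 0, 1 and 2 weeks and pericarp at 2 weeks. The 0-week leaves were taken before irradiation.

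The authors deposited log2 values per probe set, normalised by RMA per the submitters' processing notes. RMA corrects the background, sets the distributions of the arrays equal and summarises each probe set. The RMA version and which arrays were normalised together are not given in the sources used here. RMA removes any shift shared by most transcripts, so a change is measured relative to the bulk of the probe sets. The values are relative signals and not transcript numbers, and probe sets close to the background or near the top of the scale understate real folds. For arrays no read depth applies, and their number limits the precision. The array medians lay between 8.50 and 8.61 on the log2 scale. The labels name 2 or 3 biological replicates per group but do not say from which plants they came.

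The file held 10209 probe sets. The 108 control probe sets of the manufacturer were left out of the tests, which leaves 10101. A platform annotation table paired 909 of them with 1 gene symbol each, none with several, and did not list the other 9192, which are unnamed here and given by probe set ID, with _ in place of each point. The 909 probe sets stood for 803 genes, and 885 of them had a gene ID in the RefSeq gene table of the assembly SLM_r2.1, from which current symbols were taken. For 207 probe sets the only name was a LOC number. No genome was used here, so no coordinates are given. Where a gene had several probe sets, the one with the highest mean stood for it. Called probe sets of 1 gene ran in opposite directions only for FESOD, in the comparisons of 2 weeks with 0 weeks.

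The 20 arrays fell into 7 groups by their labels. Linear models were fitted with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, without covariates. The 14 leaf arrays shared a fit, the 6 pericarp arrays had their own, and the 12 arrays of 2 weeks were fitted together for comparisons between tissues. P-values were two-sided and adjusted by Benjamini-Hochberg over all probe sets tested, and an adjusted p under 0.05 was called. Values are log2 fold changes ± standard error. Tables were handled with Python 3.11.15 and pandas 2.3.3 and plots drawn with matplotlib 3.10.9. There were 10 comparisons, of which 3 set 1000 PPF against 200 PPF. The others were the 4 comparisons of irradiated with 0-week leaves, the change of the light effect in leaf from 1 to 2 weeks, its difference between leaf and pericarp, and leaf against pericarp. The 4 comparisons with 0 weeks share the 3 arrays of that group, so their overlaps were not counted.

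Genes were named by a fixed rule. In the light comparisons these were the 8 probe sets with the largest rise and the 8 with the largest fall among those called whose groups did not overlap and that had a gene name, and in the other comparisons 4 and 4. In the interactions the condition on overlap cannot be met and was dropped. If fewer than 5 passed, the 5 named probe sets with the smallest p were given as not passing. Up to 4 members of a list with the smallest p were named, and up to 2 probe sets without a gene name per direction.

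Of 30 gene lists, 20 had at least 3 measured genes and were tested with camera in limma at a preset correlation of 0.01, in 4 comparisons, with adjustment over the 80 tests. They held light-harvesting proteins, photosystem and thylakoid electron transport subunits, starch and sucrose metabolism, sugar transport, flavonoid and anthocyanin biosynthesis, carotenoid biosynthesis, antioxidant enzymes, heat shock proteins, light signalling and clock, pathogenesis-related proteins, jasmonate and wound response, ethylene biosynthesis and signalling, fruit ripening and cell wall modification, cell cycle and histones, cytosolic ribosomal proteins, nitrogen assimilation, organic acid and GABA metabolism, abscisic acid and dehydration response, and markers of trichomes and of epidermis. The other 10 lists, those for phloem and xylem and for seed among them, had fewer than 3 genes and were left out. The comparisons, lists, naming rule and most alternatives were chosen before the data were examined. List tests in the 4 comparisons with 0 weeks and in the 2 interactions were added after seeing the data and were adjusted over their 120 tests. These added tests were not rerun with dim probe sets or single arrays left out, with the 3' minus 5' index described below, or against a background of named genes. No list call in either family held with a correlation estimated per list, and the adjusted p from that test stands beside each call in the Results. Lists were matched on gene symbols and their synonyms alone, without titles, so a few members do something else than the list is named for. Those recognised are named where they appear.

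The fits were tested on simulated values made from the arrays, with normal noise drawn independently for each probe set at its SD within groups. Noise shared between genes and arrays that stand apart were not simulated, so the recovered shares are not the power on the real arrays. Of changes of 2 on the log2 scale, 92.4% were recovered in the leaf light comparison at 1 week, 92.4% at 2 weeks, 72.4% in the pericarp light comparison and 63.6% in the difference between tissues. Of changes of 1, the shares were 60.8%, 74.8%, 23.2% and 20.8%.

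The alternatives were a second quantile normalisation, equal array medians, leaving out probe sets under the 40th percentile of mean signal, eBayes with trend and robust settings, array weights, a fold minimum of 2, a fit of all 20 arrays, a fit of only the groups compared, the replicate letter as a block, and leaving out each array in turn. For lists they were an estimated correlation, fry and the mean of a gene's probe sets. Chosen after seeing the data were the 3' minus 5' index as a covariate, leaving out both arrays that stand apart, lists without mismatched members and a background of named genes. The index is the mean log2 difference between the 3' and 5' control probe sets of actin, GAPDH and EF1a on an array, which grows when RNA is degraded or copied incompletely.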

Results

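The 20 arrays held 14 of leaf and 6 of fruit pericarp from tomato plants whose kept leaf was lit at 200 or 1000 PPF. Leaf was taken before this light (0 weeks) and after 1 and 2 weeks, and pericarp after 2 weeks. Each group held 3 arrays except leaf at 1 week and 200 PPF, which held 2. Among the leaf arrays, component 1 carried 49.6% of the variance and set the 0-week leaves apart from the later ones. Pericarp 1000 PPF array A and leaf 2-week 1000 PPF array C stood furthest from the other arrays of their groups, with a standard deviation from the group mean of 0.600 and 0.421 log2. The 3' minus 5' difference of the control transcripts, used here as an RNA-quality index, averaged 2.02 in leaf at 0 weeks and 1.41 and 1.35 in leaf at 2 weeks. In pericarp it averaged 1.09 at 200 PPF and 1.70 at 1000 PPF.

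**Figure D1:**
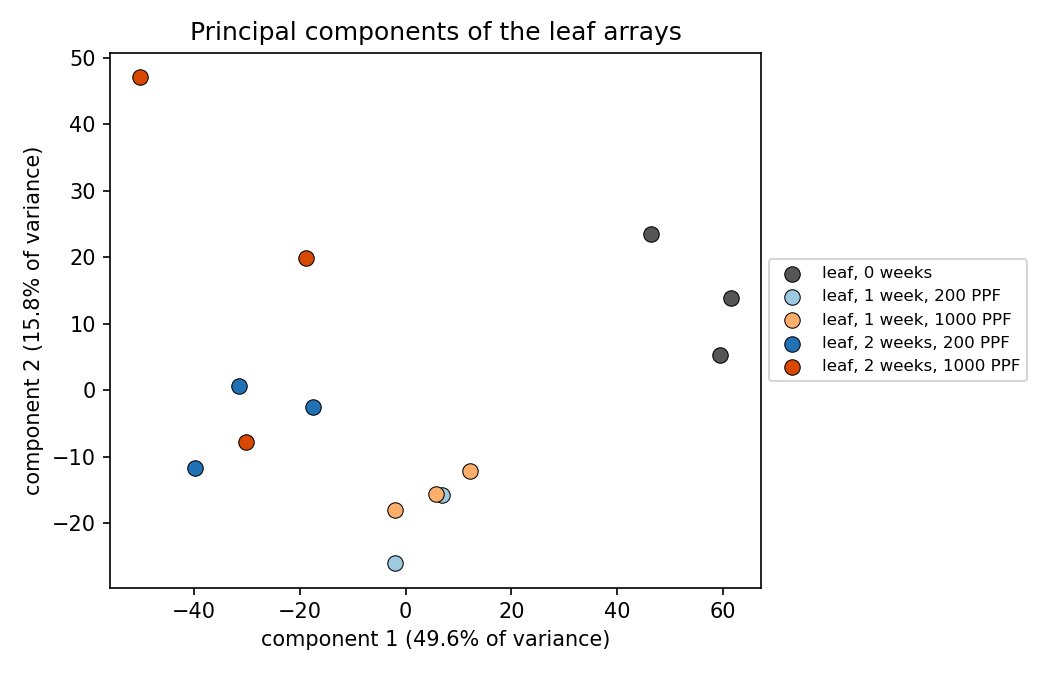
The 14 leaf arrays on their first components, with component 1 (49.6% of variance) on the horizontal axis and component 2 (15.8%) on the vertical axis. Each point is 1 array, coloured by time and light level; the 0-week arrays lay at the far end of component 1 and the light levels overlapped along it within each week.

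**Figure D2:**
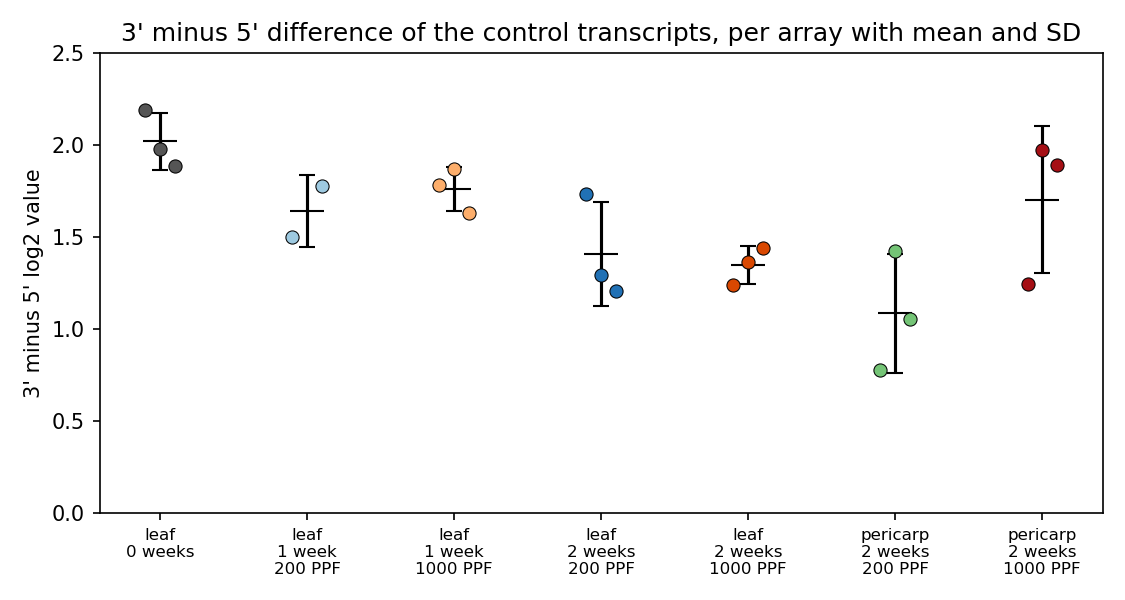
The 3' minus 5' log2 difference of the control transcripts for each of the 20 arrays, with group mean and SD. The mean was 2.02 in leaf at 0 weeks, 1.09 in pericarp at 200 PPF and 1.70 in pericarp at 1000 PPF.

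After 1 week, leaves at 1000 PPF (n = 3) and 200 PPF (n = 2) differed in 2 probe sets, both lower at 1000 PPF and both without a gene name. LesAffx_8708_1_S1_at fell by 1.42 ± 0.14 log2 (SE; adjusted p = 0.00594) and Les_5145_1_S1_at fell by 1.06 ± 0.14 (adjusted p = 0.0425). LesAffx_8708_1_S1_at was dim, under the 40th percentile of mean signal in leaf. So were CycA2, CDKB1, CDKB2, PE1, PLDa2, HSP17.4 and HSP21, which are given below. With dim probe sets left out, 1 of the 3 list calls given below remained. As groups, the cell cycle, cell wall and pathogenesis-related genes stood higher at 1000 PPF in the list test, although no member passed, and none passed when adjusted over the list alone. For the cell cycle genes the adjusted p was 0.0306, and 0.293 with an estimated correlation. Of these 7 of 11 had positive values, led by the proliferation marker PCNA (0.80 ± 0.28) and the cyclin CycA2 (0.55 ± 0.18), with the kinases CDKB1 at 0.62 ± 0.39 and CDKB2 at 0.74 ± 0.51. For the cell wall genes the adjusted p was 0.0194, and 0.293 with an estimated correlation. Here 30 of 43 were positive, among them XTH3 (2.25 ± 0.88) and the expansin EXP5 (0.66 ± 0.28), while the pectinesterase PE1 stood at -0.31 ± 0.14. PGH1 (0.24 ± 0.10), which came into that list by its symbol, encodes the glycolytic enzyme enolase. The genes called cell wall genes here are the list of fruit ripening and cell wall modification, which also holds the ripening regulators RIN and NOR. For the pathogenesis-related genes the adjusted p was 0.0451, and 0.806 with an estimated correlation. There 8 of 9 were positive, including the chitinase CHI3 (1.18 ± 0.58), the PR-5 gene LOC543878 (0.91 ± 0.55) and PR-P2 (1.64 ± 1.02).

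The named genes with the smallest p in the 1-week leaf, none passing, were ER5 (-1.87 ± 0.38, adjusted p = 0.244), WRKYIId-1 (1.17 ± 0.32, 0.379), the iron reductase gene FRO1 (1.13 ± 0.25, 0.319), the abscisic acid response factor AREB1 (-0.98 ± 0.24, 0.319) and PLDa2 (-0.75 ± 0.18, 0.319). The 6 genes of the flavonoid list had positive values (adjusted p = 0.0678), but 2 of them, CHI3 and CHI9, are chitinases that came in by their symbols and also stand among the pathogenesis-related genes. The small heat shock genes HSP17.4 and HSP21 stood at 1.79 ± 0.98 and 1.18 ± 0.66 (heat shock list, adjusted p = 0.406). Of 742 probe sets with unadjusted p under 0.05, against 505 expected with no effect at all, limma with BH adjustment left 0 higher and 2 lower. That count was 0 without 200 PPF array B or C, each of which leaves a lone array assumed to vary like the other groups. It was 8 without 1000 PPF array A, 1 without array B or C, and 50 (10 higher, 40 lower) with array weights. The cell cycle call was lost without 200 PPF array B (adjusted p = 0.0711) or 1000 PPF array C (0.194). The pathogenesis-related call was lost without 200 PPF array C (0.246), 1000 PPF array A (0.133) or 1000 PPF array C (0.194). Through the shared fit and adjustment it was also lost without leaf 2-week 200 PPF array A, B or C, leaf 2-week 1000 PPF array B or pericarp 200 PPF array B or C (0.0502 to 0.0999). The flavonoid list passed without 200 PPF array B (0.0363), 1000 PPF array B (0.0145) or leaf 2-week 1000 PPF array C (0.0398). Values of single genes also leaned on single arrays: without 1000 PPF array C CDKB1 was at 0.19, CDKB2 at 0.32 and XTH3 at 1.35, without 200 PPF array C EXP5 was at 0.34, and without 1000 PPF array B HSP17.4 was at 0.78 and HSP21 at 0.24.

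After 2 weeks (n = 3 and 3), no single probe set passed between leaves at 1000 and 200 PPF, but the ethylene genes as a group stood lower at 1000 PPF (adjusted p = 0.0194, and 0.806 with an estimated correlation). Only 8 of the 36 ethylene genes had positive values, with a median of -0.18. Among the lowest were the response factors ERF3 (-1.11 ± 0.35) and ERF2 (-0.98 ± 0.17) and the ACC synthase ACS6 (-0.87 ± 0.18), and 2 genes were lower when adjusted over the list alone. Another ACC synthase, ACS2, stood on the other side at 1.13 ± 0.40. Light signalling genes gave 2 lower members when adjusted over the list alone, the blue light receptor Cry1b (-0.80 ± 0.25) and the repressor COP1 (-0.42 ± 0.13). CRY1A was at -0.22 and HY5 at 0.54, and the list itself had an adjusted p of 0.325.

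The smallest adjusted p among named genes of the 2-week leaf, 0.113, belonged to bZIP1 (-1.16 ± 0.19) and ERF2; BL3 (0.41 ± 0.10) had 0.12 and EREB (1.48 ± 0.36) had 0.135. In carotenoid synthesis, Psy1 stood at 0.77 ± 0.29 and NSY at -0.51 ± 0.19. The defence genes LOC543878 and PR-P2 stood at -1.45 ± 0.49 and 1.99 ± 0.91. In the jasmonate and wound list, matched by symbol, values were positive for loxC (0.71 ± 0.37), LOX1.1 (1.40 ± 0.74) and TD2 (1.37 ± 0.68). The list had an adjusted p of 0.435. With limma 0 probe sets passed, and 1460 had an unadjusted p under 0.05, against 505 expected with no effect at all. Probe sets are not independent, and this excess was not tested. Without 1000 PPF array A, 186 passed (43 higher, 143 lower), among them bZIP1 (-1.26), ERF2 (-0.93), ACS6 (-1.02), ERF3 (-1.53), LOC543878 (-2.21) and ACS2 (1.60). The ethylene call was lost without 200 PPF array A (adjusted p = 0.114) or 1000 PPF array B (0.297), and the jasmonate list passed without 1000 PPF array A (0.0244). Without 1000 PPF array C, which stands apart, several values shrank: LOX1.1 to 0.28, TD2 to 0.48, PR-P2 to 0.92, LOC543878 to -0.95, ACS2 to 0.68, Psy1 to 0.47, HY5 to 0.29 and Cry1b to -0.49.

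The light effect in leaf differed between the weeks in 1 probe set, LesAffx_8708_1_S1_at, whose effect was 1.90 ± 0.19 log2 higher at 2 weeks (adjusted p = 0.00598; n = 2 and 3 at 1 week, 3 and 3 at 2 weeks). The 1-week arrays that gave its fall at 1 week enter this difference too. It is a dim probe set in leaf, and 0 passed with dim probe sets left out. In list tests added after the values were seen, the light effect on 3 groups was lower at 2 weeks than at 1 week. For the ethylene genes the adjusted p was 0.00196, and 0.696 with an estimated correlation, with ACS6 (-1.19 ± 0.28) and ERF2 (-1.04 ± 0.25) lower when adjusted over the list alone. For the cell cycle genes it was 0.0136, and 0.524 with an estimated correlation. Of the 11, 0 were positive, the median was -0.25 and CycA2 (-0.86 ± 0.24) was lower when adjusted over the list alone. For the cell wall genes it was 0.0136, and 0.587 with an estimated correlation. Of the 43, 13 were positive and XTH3 stood at -4.47 ± 1.18. The stress response factor genes CBF1 (-6.07 ± 1.33) and DREB3 (-1.47 ± 0.33), WRKYIId-1 (-1.91 ± 0.43) and the subtilase gene sbt3 (-1.44 ± 0.33) each had an adjusted p of 0.108, and bZIP1 (-1.58 ± 0.29) had 0.087. The count of 1 became 0 without 1-week 200 PPF array B or C, 84 without 1-week 1000 PPF array A, 57 without 2-week 1000 PPF array A and 3 without 2-week 1000 PPF array B.

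In pericarp at 2 weeks (n = 3 and 3), the light-harvesting genes stood lower at 1000 PPF than at 200 PPF and the ethylene genes higher, while no single probe set passed. The LEDs lit the kept leaf, so a light effect in pericarp here means a difference with the light level of that leaf. The light that reached the fruit and the stage of the fruit were not examined. None of the list calls given here held with the RNA-quality index in the fit. The 3 light-harvesting genes, CAB4 (-0.90 ± 0.21), CAB6A (-0.63 ± 0.22) and CAB5 (-1.03 ± 0.36), were all lower when adjusted over the list alone (list adjusted p = 0.0194, and 0.806 with an estimated correlation). The 6 photosystem genes were all negative (adjusted p = 0.0396, and 0.925 with an estimated correlation), among them plastocyanin PETE (-0.63 ± 0.17), PSBP (-0.40), PSBO (-0.31) and the photosystem I gene LOC543978 (-0.29). Of the 36 ethylene genes 28 were positive (adjusted p = 0.0195, and 0.806 with an estimated correlation), including the signalling factor EIL2 (0.83 ± 0.23), the ACC synthase ACS4 (1.01 ± 0.33) and the ACC oxidase ACO4 (0.78 ± 0.26), with JERF3 at -0.45 ± 0.16.

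The named pericarp genes with the smallest p, none passing over the whole array, included wall, flavonoid and defence genes. The self-incompatibility homologue sph1 was at -6.80 ± 0.71 (adjusted p = 0.104), the endo-mannanase MAN2 at -4.80 ± 0.56 (0.139) and chalcone synthase CHS1 at -3.54 ± 0.32 (0.0692). The osmotin-like NP24-I was at -2.92 ± 0.40 (0.151) and the fruit pectinesterase PE1 at 7.05 ± 1.16 (0.232). Adjusted over its list alone CHS1 was lower, with DFR at -1.37 ± 0.69 (flavonoid list, adjusted p = 0.325). Among cell wall genes PE1 and the beta-galactosidase TBG1 (0.94 ± 0.19) were higher and the xyloglucan enzyme LOC543916 (-1.56 ± 0.27) and the cellulase Cel2 (-1.82 ± 0.41) lower, each adjusted over the list alone. The list had no single direction (adjusted p = 0.948). Also adjusted over the list alone, PR1b1 (5.25 ± 1.11) was higher, and the trichome marker MTS1 (-2.65 ± 0.68), the plastid glutamine synthetase GS2 (-1.29 ± 0.39) and the glutamate decarboxylase yfe37 (-1.26 ± 0.33) were lower. Cell cycle genes had a median of -0.79 (adjusted p = 0.114), with CYCD3 at -1.52 ± 0.37, CDKB2 at -2.07 ± 0.64, CycA1 at -1.67 ± 0.52 and CDKB1 at -1.23 ± 0.41. The threonine deaminase TD2 stood at -4.23 ± 1.14, and all 3 epidermis markers were negative (median -1.92, adjusted p = 0.322).

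With limma 0 probe sets passed in pericarp, and 1334 had an unadjusted p under 0.05, against 505 expected with no effect at all, an excess that was not tested. Without 1000 PPF array A, the array furthest from its group, 18 passed (9 higher, 9 lower), among them sph1 (-7.46, adjusted p = 0.0189), CHS1 (-3.34, 0.0408) and PE1 (8.48, 0.00147). Without 200 PPF array B 2 passed, and a fit over all 20 arrays called 583. That fit gives pericarp a spread shared with leaf, where arrays lay closer to their group means. The mean SD from the group mean was 0.155 to 0.363 log2 in the leaf groups, and 0.373 and 0.453 in pericarp at 200 and 1000 PPF. The 583 may therefore overstate what passes in pericarp. The index was 1.09 at 200 PPF and 1.70 at 1000 PPF. At 1000 PPF it was 1.24 on array A and 1.97 and 1.89 on arrays B and C. In fits of pericarp with the index, its part and that of array A are therefore not told apart. With the index in the fit the ethylene, light-harvesting and photosystem lists had adjusted p of 0.587, 0.148 and 0.446, and 2 other lists passed, flavonoid and epidermis (0.0442 each, both lower). Single values moved as well with the index, to -0.61 for CDKB2, -0.75 for CycA1, -0.52 for CDKB1, -0.25 for CAB6A, -0.36 for PETE, -0.19 for PSBP, -0.02 for LOC543978, 0.53 for EIL2 and 1.31 for ACO4. PE1 was then at 4.43, TBG1 at 0.61, Cel2 at -0.83 and TD2 at -2.34, and DFR turned to 0.36. The light-harvesting call was lost without 200 PPF array B (0.0734). The photosystem call was lost without 200 PPF array B (0.142), 200 PPF array C (0.127), 1000 PPF array B (0.226) or 1000 PPF array C (0.0510). The cell cycle list passed without 200 PPF array A (0.0291) or 1000 PPF array C (0.0414), and flavonoid (0.0304) and epidermis (0.0414) without 1000 PPF array C.

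**Figure D3:**
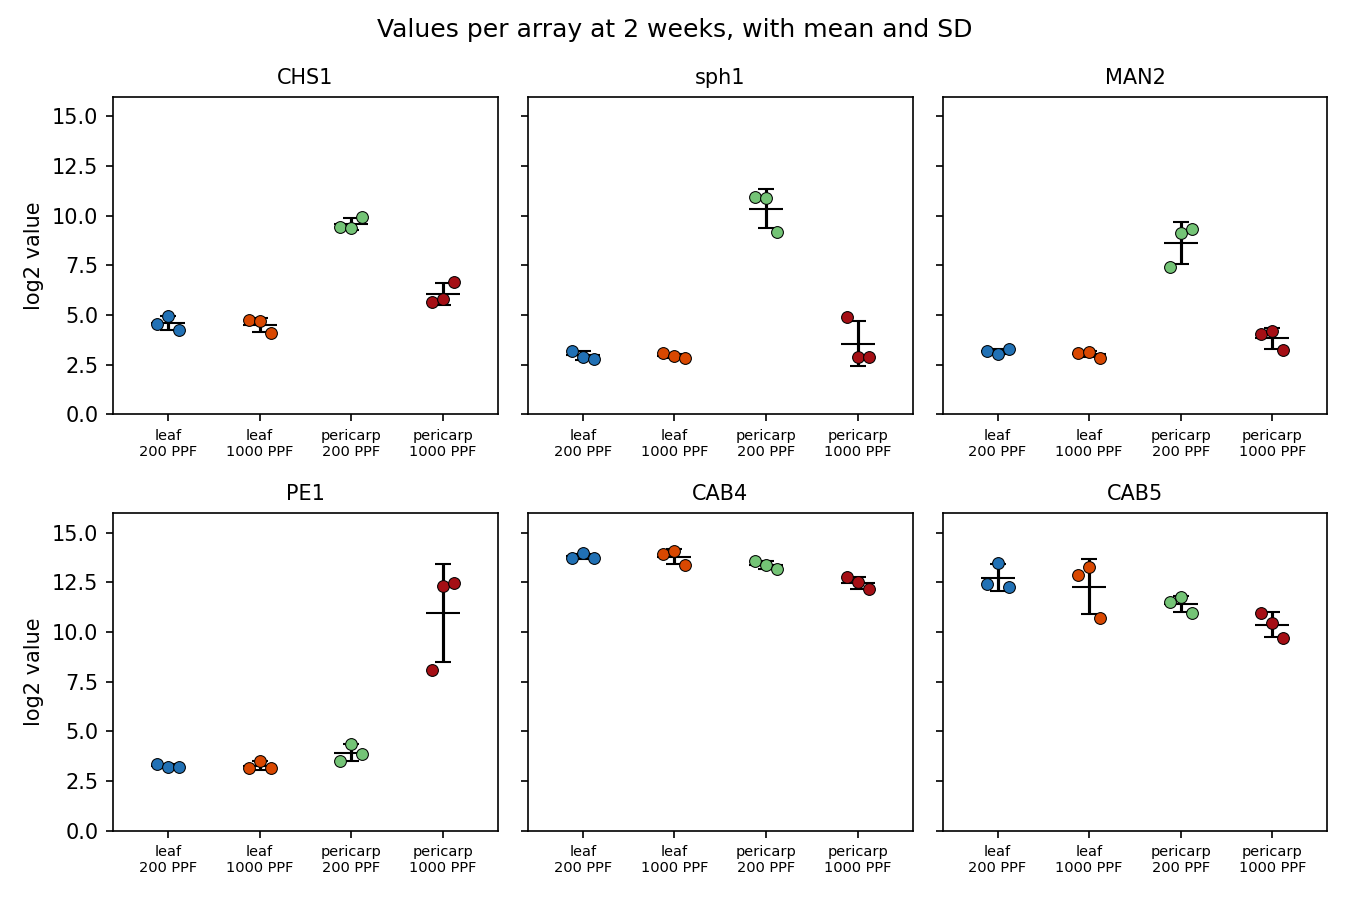
Log2 values per array of CHS1, sph1, MAN2, PE1, CAB4 and CAB5 in leaf and pericarp at 2 weeks and 200 or 1000 PPF, with group mean and SD (n = 3). In pericarp sph1 stood at -6.80 log2 at 1000 PPF against 200 PPF and PE1 at 7.05, while in leaf all of CHS1, sph1, MAN2 and PE1 stayed low.

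The light effect differed between leaf and pericarp in 5 probe sets at 2 weeks (n = 3 in each of 4 groups). Relative to pericarp, the effect of 1000 PPF in leaf was higher for sph1 (6.77 ± 0.79 log2, adjusted p = 0.0218), MAN2 (4.65 ± 0.62, 0.0333) and CHS1 (3.45 ± 0.43, 0.0218), and lower for the unnamed Les_5956_2_S1_at (-2.70 ± 0.24, 0.00402) and LesAffx_13721_1_S1_at (-1.76 ± 0.22, 0.0218). The ethylene genes as a group had a lower light effect in leaf than in pericarp (adjusted p = 0.00074, and 0.655 with an estimated correlation). Only 6 of 36 were positive with a median of -0.47, and ACS6 (-1.38 ± 0.36), ERF3 (-1.44 ± 0.48), EIL2 (-1.03 ± 0.30) and JERF1 (-0.72 ± 0.23) were among the lowest. This list test uses the arrays of the ethylene calls within leaf and within pericarp, so it is not separate evidence. It was not rerun with the index or without single arrays. Not passing were bZIP1 (-1.89 ± 0.28, adjusted p = 0.068), PE1 (-7.02 ± 1.29, 0.136), Cry1b (-1.49 ± 0.38) and COP1 (-0.86 ± 0.32). In leaf sph1 (2.97 and 2.93 at 200 and 1000 PPF), MAN2 (3.17 and 3.02) and CHS1 (4.60 and 4.51) had low values at both light levels and little room to fall, so their differences restate the pericarp folds and are no measure of a light response in leaf. The unnamed 2 were well above that in leaf (8.84 and 8.35 for Les_5956_2_S1_at, 9.48 and 9.33 for LesAffx_13721_1_S1_at). These leaf means moved little with light, so their differences also came mostly from pericarp. With the index in the fit 0 of the 5 passed in limma, 649 having an unadjusted p under 0.05, at similar sizes (sph1 6.03 ± 0.92, CHS1 3.60 ± 0.54, MAN2 4.99 ± 0.77, Les_5956_2_S1_at -2.47 ± 0.28, LesAffx_13721_1_S1_at -1.73 ± 0.27). The count was 64 without pericarp 1000 PPF array A, 21 without pericarp 200 PPF array B, 13 without leaf 1000 PPF array A, 2 without pericarp 200 PPF array A, 3 without pericarp 200 PPF array C, and 1 without pericarp 1000 PPF array B or any of leaf 200 PPF arrays A, B and C and leaf 1000 PPF arrays B and C.

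Across all probe sets the light effects of the 3 comparisons had little in common, and the rotation test fry in limma called 0 of the 7 lists that camera called for light. Against a background of the named genes, chosen after the values were seen, camera called 0 of those 7 as well. The correlation of log2 fold changes was -0.128 between leaf at 1 and 2 weeks (54.5% of the same sign), -0.190 between leaf and pericarp at 2 weeks (42.2%) and -0.0176 between leaf at 1 week and pericarp (48.7%). By rank it was 0.0877, -0.214 and -0.0176, so the sign for the leaf weeks depends on the statistic. No array is shared between these comparisons, but genes are not independent replicates. Cry1b (-0.80 and 0.69) and TD2 (1.37 and -4.23) were among the named genes with values on opposite sides in leaf and pericarp at 2 weeks. With the index in both fits the leaf and pericarp correlation was -0.0300.

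From 0 weeks onward, leaf expression changed widely at both light levels, with carotenoid genes falling and ribosomal protein genes rising. The 4 comparisons share the 3 arrays of 0-week leaf, so they are not separate evidence. At 200 PPF 2801 probe sets changed by 1 week (1606 higher, 1195 lower; n = 2 and 3) and 4627 by 2 weeks (2453 higher, 2174 lower; n = 3 and 3). At 1000 PPF the counts were 2632 (1407 higher, 1225 lower) and 4791 (2591 higher, 2200 lower), each with n = 3 and 3. The gibberellin 20-oxidase gene 20ox-2 gave the largest fall of a named gene in all 4, by -5.06 ± 0.46 and -4.67 ± 0.41 at 200 PPF (adjusted p = 0.000225 and 2.3e-05) and -4.96 ± 0.41 and -4.92 ± 0.41 at 1000 PPF (0.000152 and 1.99e-05). GA20OX1, a second gene of that enzyme family, changed by -3.03 ± 0.88, -3.46 ± 0.79, -3.12 ± 0.79 and -3.78 ± 0.79 in that order.

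Large rises of named genes in leaf at 200 PPF were those of ER5 (3.86 ± 0.38, adjusted p = 0.000284), the allene oxide synthase AOS (3.41 ± 0.60), Ve1 (3.10 ± 0.50) and EREB (3.03 ± 0.40) at 1 week. At 2 weeks they were the rises of ER5 (4.19 ± 0.34, 1.87e-05), THT1-3 (4.05 ± 0.63), cevi19 (3.97 ± 0.73) and DES (3.89 ± 0.87). At 1000 PPF they were those of EREB (3.60 ± 0.36), DES (3.41 ± 0.87), PTI5 (2.99 ± 0.69) and JA2 (2.79 ± 0.31) at 1 week. By 2 weeks they were those of TSI-1 (5.35 ± 0.68, 0.000112), THT1-3 (4.47 ± 0.63), pip1 (4.24 ± 0.46) and cevi19 (4.04 ± 0.73). Large falls beside the oxidases were those of TD2 (-4.72 ± 0.76 at 200 PPF and -4.09 ± 0.68 at 1000 PPF) at 1 week, the metallothionein MT3 (-3.12 ± 1.05) at 1 week and 200 PPF and ST2 (-2.56 ± 0.49) at 1 week and 1000 PPF. At 2 weeks they were those of the cellulase Cel1 (-3.81 ± 0.30 and -3.64 ± 0.30), Cel2 (-3.42 ± 0.64) at 200 PPF and fsm1 (-3.96 ± 0.84) at 1000 PPF.

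Of the 10 carotenoid genes, 6 fell by 1 week at either light level and 9 by 2 weeks, with 1 higher at 200 PPF and 2 weeks. The list test, added after the values were seen, gave an adjusted p of 0.000767 at 1 week and 200 PPF and 0.000431 in the other 3 comparisons, and 0.655 with an estimated correlation in each. Over 1 week at 200 PPF and 1000 PPF and 2 weeks at 200 PPF and 1000 PPF, the lycopene cyclase LCY1 changed by -0.75, -0.83, -1.34 and -1.13. The desaturase PDS changed by -0.72 ± 0.11 and -0.82 ± 0.10 at 1 week and by -0.98 ± 0.10 at 2 weeks and 200 PPF. The de-epoxidase VDE fell by 2.55 ± 0.46 at 1 week and 3.24 ± 0.41 at 2 weeks at 200 PPF, and the hydroxylase CrtR-b1 by 2.10 and 2.20 at 2 weeks. Ribosomal protein genes rose in 4, 4, 4 and 5 of 5, with RPL3 up by 0.60, 0.65, 0.73 and 0.76. The list had adjusted p of 0.0381, 0.00963, 0.0747 and 0.033, and 0.696, 0.655, 0.696 and 0.696 with an estimated correlation.

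**Figure D4:**
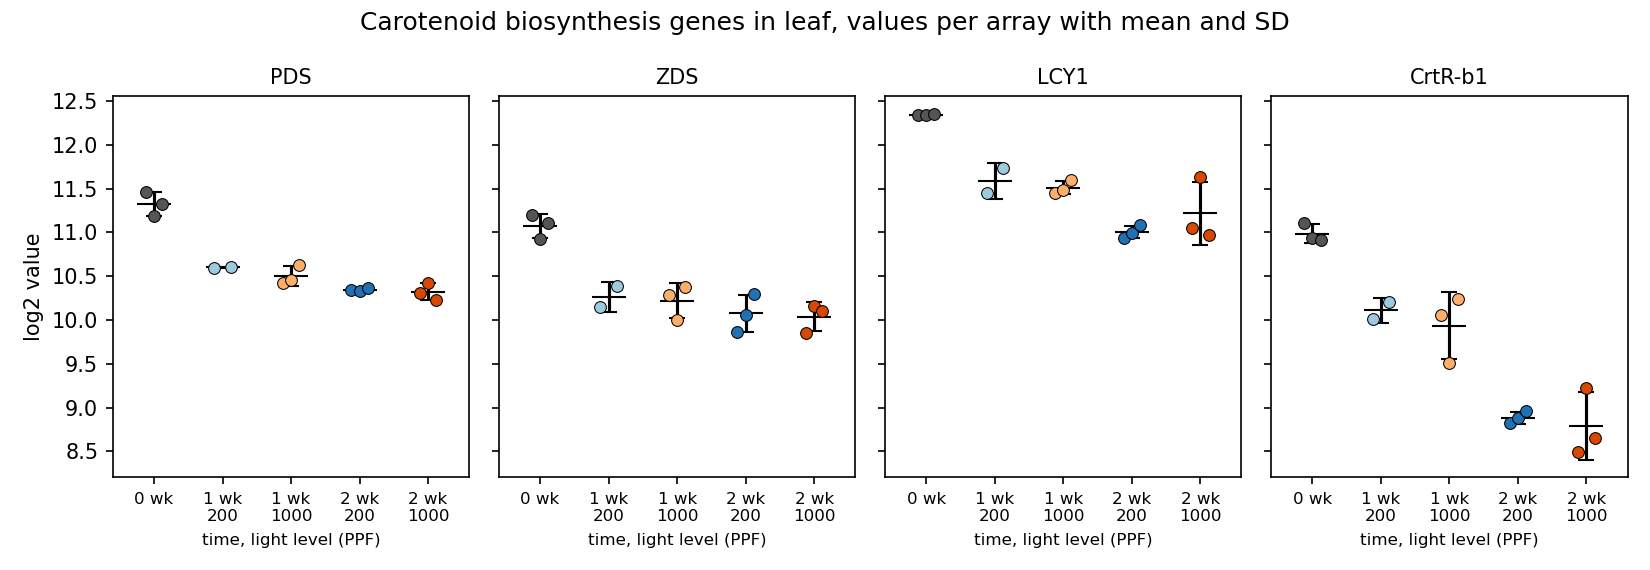
Log2 values per array of the carotenoid genes PDS, ZDS, LCY1 and CrtR-b1 in leaf at 0, 1 and 2 weeks and 200 or 1000 PPF, with group mean and SD (n = 2 at 1 week and 200 PPF, otherwise 3). At 2 weeks CrtR-b1 stood at -2.10 log2 at 200 PPF and -2.20 at 1000 PPF against 0 weeks.

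Ethylene genes rose more often than they fell: 9, 13, 18 and 15 of 36 were higher and 1, 0, 1 and 3 lower in the same order of comparisons. Their list had adjusted p of 0.0377, 0.00251, 0.00963 and 0.207, and 0.696 in the first 3 and 0.716 in the last with an estimated correlation. The response factor PTI4 rose by 2.13, 2.04, 2.07 and 1.84 and the receptor ETR5 by 1.28 and 1.27 at 1 week, and the receptor ETR2 fell by 1.21 and 0.92 at 2 weeks. Cell wall genes fell in 10, 8, 12 and 14 of 43 and rose in 0, 1, 5 and 1, with list adjusted p of 0.00161, 0.0322, 0.104 and 0.0307, and 0.524, 0.587, 0.655 and 0.587 with an estimated correlation. Their falls included XET4 (-1.89, -2.05, -2.28 and -2.20), the expansins EXP5 (-1.98 and -1.32 at 1 week) and EXP12 (-2.69 at 1 week and 200 PPF) and Cel1 (-1.96 and -2.25 at 1 week). Light signalling genes fell in 1, 4, 7 and 7 of 9, with list adjusted p of 0.17, 0.0661, 0.042 and 0.0136, and 0.696 with an estimated correlation. At 2 weeks these included CO1 at both light levels (-1.70 and -2.20), HY5 (-1.10), DET1 (-0.58) and DDB1 (-0.41) at 200 PPF, and Cry1b (-1.07), COP1 (-0.79) and CRY1A (-0.50) at 1000 PPF.

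Starch and sucrose genes went both ways by 2 weeks, with 3 of 11 higher and 4 lower at 200 PPF and 2 higher and 4 lower at 1000 PPF (adjusted p = 0.535 and 0.457 in the added list tests). Of 5 sugar transport genes 1 was higher and 2 lower at 200 PPF, and 1 higher and 1 lower at 1000 PPF (0.857 and 0.965). The sucrose synthase sus3 (2.06 and 2.18 at 200 and 1000 PPF) and the hexose transporter HT2 (3.05 and 3.19) rose, while the invertase LIN8 (-2.58 and -2.90), the starch synthesis gene AGPL3 (-1.95 and -2.44), the sucrose phosphate synthase SPS (-1.04 at 1000 PPF) and the sucrose transporter SUT4 (-0.79 and -0.72) fell. The glucanase GluB rose by 2.27 and 2.22 and the protease P69A fell by 1.30 and 1.16. LEA14 rose by 2.42 and 2.05, and NCED1, of abscisic acid synthesis, fell by 1.44 and 1.46. Of the photosystem genes 2 of 6 fell at 200 PPF and 4 of 6 at 1000 PPF, among them PETE (-0.57 and -0.66) and PsbQ (-0.40 and -0.43). These calls lay near the threshold: at 200 PPF that of PETE was lost without 0-week array C or 200 PPF array A or C (adjusted p = 0.0505, 0.0643 and 0.0506), and that of PsbQ without 0-week array B or C or 200 PPF array A or C (0.0534 to 0.0670). At 1000 PPF PsbQ did not pass without 1000 PPF array C (0.0552), after a second quantile normalisation (0.0629) or in 2 further ones of 16 alternatives, and PSBO and PSBP did not pass in 6 and 11 of the 16. At 1 week and 200 PPF the count was 371 without the 200 PPF array B, 1452 without array C and 1773 without 0-week array C, the first 2 leaving a lone array assumed to vary like the other groups. VDE, LCY1, EXP12 and XET4 did not pass without array B. MT3 did not pass without any 1 of the 5 arrays, nor GA20OX1 without 200 PPF array B or C or 0-week array A or C. With all 20 arrays in 1 fit Cel1 did not pass at 1 week (adjusted p = 0.190 at 200 PPF and 0.0961 at 1000 PPF). At 1 week and 1000 PPF the count was 1451 without 1000 PPF array B, 1751 without 1000 PPF array A, 1683 without 0-week array A and 1607 without 0-week array C. DES did not pass without 1000 PPF array A or 0-week array C, nor GA20OX1 without 1000 PPF array B or 0-week array C. With the index in the fit 2206 and 2178 probe sets passed at 2 weeks. Of the genes given, cevi19, Cel2, SUT4, NCED1, PsbQ, PETE, HY5, DET1 and DDB1 then no longer passed at 200 PPF, nor cevi19, fsm1, ETR2, PTI4, COP1, CRY1A, SUT4, NCED1 and PsbQ at 1000 PPF.

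Leaf and pericarp at 2 weeks differed in 4814 probe sets, 2366 higher and 2448 lower in leaf (n = 6 and 6, light level in the fit). Higher in leaf were CEVI-1 (8.90 ± 0.23 log2, adjusted p = 1.14e-09), ER1 (7.65 ± 0.43), the chitinase CHI3 (7.55 ± 0.62) and the carbonic anhydrase ca2 (7.48 ± 0.40). Lower in leaf were the fruit genes 2A11 (-10.82 ± 0.21, 1.02e-10), matriochka (-10.22 ± 0.13), TPRP-F1 (-10.09 ± 0.16) and TPP3 (-9.22 ± 0.73). All 9 pathogenesis-related genes were higher in leaf (adjusted p = 0.00014, and 0.293 with an estimated correlation), among them LOC543878 (7.62), GluB (7.03) and P69A (2.71). So were all 6 photosystem genes (0.0194, and 0.806 with an estimated correlation), including LOC543978 (0.73), PSBP (0.72) and PSBR (0.68). The 3 nitrogen genes were higher too (0.0306, and 0.293 with an estimated correlation), namely the ammonium transporter AMT1-2 (5.11 ± 0.38), GS2 (2.60) and the glutamate dehydrogenase gdh1 (1.24). The 3 light-harvesting genes were higher as well, CAB5 by 1.61, CAB4 by 0.88 and CAB6A by 0.83, with a list adjusted p of 0.138. In leaf CAB4 and CAB6A lay near the top of the scale, where folds are understated. The list passed without leaf 1000 PPF array C (0.0490), and fry called it together with the trichome and the starch and sucrose lists.

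Cell cycle and cell wall genes were lower in leaf than in pericarp. Of 11 cell cycle genes 9 were lower, and 10 when adjusted over the list alone (list adjusted p = 0.00394, and 0.293 with an estimated correlation), among them CDKB1 (-2.57 ± 0.27), CycA1 (-2.44), CYCD3 (-2.23 ± 0.21) and CycA2 (-1.71). Of 43 cell wall genes 19 were lower and 4 higher (0.0396, and 0.806 with an estimated correlation), with EXPA6 (-3.95), EXP5 (-2.39) and EXPA3 (-1.95) lower. TAGL1 (-7.67 ± 0.09), the lowest in that list, encodes a MADS-box factor of fruit development and not a wall enzyme. The call was lost with the enolase PGH1 out of this list and mismatched members out of others (0.0584), TAGL1 being kept, and without pericarp 200 PPF array C (0.0502), leaf 1000 PPF array A (0.0583) or leaf 1000 PPF array B (0.0565). Of the 5 camera list calls between leaf and pericarp, 2 remained with dim probe sets left out and 2 against a background of the named genes.

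Several metabolic groups split between leaf and pericarp. Of 11 starch and sucrose genes 4 were higher and 5 lower in leaf (list adjusted p = 0.747), with the invertases lin5 (-8.29 ± 0.44) and LIN7 (-3.40 ± 0.27) and the sucrose synthase LOC543961 (-6.43 ± 0.20) lower and the invertase Wiv-1 (5.73 ± 0.33) higher. Of 5 sugar transport genes HT2 was higher (6.38 ± 0.44) and HT3 lower (-1.24 ± 0.18; list 0.834). The flavonoid list had 2 of 6 higher and 3 lower (0.886; median -0.78, mean 0.32), but the 2 higher were the chitinases CHI3 and CHI9 (4.16), counted there by their symbols. Of the other 4, none was higher and 3 were lower, among them CHS1 (-3.26 ± 0.21). Of 16 genes in the jasmonate and wound list 7 were higher and 2 lower (0.593), with AOS higher (3.31) and the lipoxygenases loxC (-2.71) and LOXB (-5.02), matched by symbol, lower. The trichome list had 2 of 3 lower (0.241), MTS1 (-2.41 ± 0.38) and CPS (-2.57 ± 0.49), the latter an enzyme of gibberellin synthesis. The epidermis list had 1 of 3 higher, the lipid transfer protein TSW12 (5.95 ± 0.62; 0.698). Higher and lower members numbered 4 and 0 of 10 carotenoid genes (0.468), 10 and 8 of 36 ethylene genes (0.747), 4 and 4 of 9 light signalling genes (0.932). They numbered 3 and 2 of 11 antioxidant genes (0.834), 2 and 1 of 4 abscisic acid genes (0.932; median -0.34, mean 0.18) and 1 and 1 of 6 GABA genes (0.687). In the heat shock list 1 of 5 was lower, HSP21 (-2.15 ± 0.19; 0.687), and in the ribosomal list 2 of 5 were lower (0.698).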

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

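The tests of how gene values followed the 3' minus 5' index and of the array standing apart were set before they were run, but their repeats on chosen probe sets, among them all with folds of at least 2 log2, and on 3 further time comparisons, the fits with the index as a covariate and the list tests on how the light effect differed between weeks or tissues were chosen after the result was seen.

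The light effect in leaf changed between 1 and 2 weeks in 1 probe set, LesAffx_8708_1_S1_at at 1.90 log2, and in 3 gene lists, the cell cycle (adjusted p = 0.0136), ethylene (0.00196) and cell wall genes (0.0136). At 2 weeks it differed between leaf and pericarp in 5 probe sets, sph1 (6.77), MAN2 (4.65), CHS1 (3.45), Les_5956_2_S1_at (-2.70) and LesAffx_13721_1_S1_at (-1.76), and for the ethylene genes (adjusted p = 0.00074). In leaf sph1, MAN2 and CHS1 had low values at both light levels (2.93 to 4.60), so these 3 differences restate the folds of pericarp. The groups held 2 or 3 arrays, and no list call held with an estimated correlation. The list tests on these differences use the arrays of the light comparisons, so they are not separate evidence. They were not rerun with the index or without single arrays.

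Leaf at 0 weeks differed from leaf at 1 and 2 weeks in 2632 to 4791 probe sets at both light levels, and the index fell over the same time from 2.02 to 1.35. If RNA quality made these changes, folds predicted from the spread of the index within groups should follow the measured ones. Across probe sets the correlation for 2 weeks at 200 PPF was -0.267, and -0.345 to 0.00211 when leaving out 1 array, so the measured folds did not follow the prediction. For 1 week at 200 PPF it was -0.287, for 1 week at 1000 PPF -0.281 and for 2 weeks at 1000 PPF -0.341, with 0.0381 the highest when leaving out 1 array. The prediction rests on a small spread of the index within leaf groups (SD 0.102 to 0.283), and noise in it lowers such a correlation by itself. A part of RNA quality is therefore not excluded. With the index as a covariate the counts at 2 weeks fell from 4627 and 4791 to 2206 and 2178. Time in the light, leaf age, harvest date and the step from growth at 450 to 500 PPF to the LEDs run together in these groups. The time since the other leaves and trusses were taken off may run with them. Each of these could have a part, which was not tested, and they cannot be told apart here.

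In pericarp the 5 named genes with the smallest p had folds of 2.92 to 7.05 log2 in size with no probe set called. RNA quality might have a part: the index differed between the light levels by 0.616, and predicted and measured folds correlated at 0.209 over all probe sets (-0.00531 to 0.465 when leaving out 1 array). At 1000 PPF the index was 1.24 on array A, which stands apart, and 1.97 and 1.89 on arrays B and C. Within that group the index therefore largely sets array A against the other arrays, and the index and array A are not told apart by this prediction. The correlation was 0.521 over the 1334 probe sets with unadjusted p under 0.05 (0.105 to 0.750) and 0.0276 over the 138 with folds of at least 2 log2 in size (-0.241 to 0.599), so the question stays open. Without the array standing apart, 1000 PPF array A, the median size of those 138 was 99.2% of that with it (84.8% to 114% without each other array), which argues against this array as the source of the folds; the 5 genes, at 102%, were picked by p and decide nothing. Without it 18 probe sets passed, so its part in the missing calls, and what more arrays would show, stay open. Whether the stage of the fruit differed between the light levels was not examined.

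Light effects in leaf and pericarp at 2 weeks had a weak negative correlation across probe sets, -0.190. With the index in both fits it was -0.0300, and -0.165 to 0.0951 when leaving out 1 array, so RNA quality is a candidate explanation of the negative value. In the pericarp fit alone the index took it to -0.0455 and in the leaf fit alone to -0.161. The index also raised the mean SE in pericarp from 0.293 to 0.383, and added noise lowers a correlation by itself. These 2 readings are not told apart here.

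The arrays were regrouped to ask how often such counts arise by chance. All 10 splits of 6 arrays were run, so no share under 0.05 can be reached. For the light effect in leaf at 2 weeks and in pericarp the real count was 0. Every split has at least as many, so 10 of 10 was fixed beforehand and decides nothing. The highest count in another split was 9 in leaf and 0 in pericarp. The share was 1 of 10 for each time effect tested, with 2632, 4627 and 4791 against at most 0, 0 and 1 in other splits. For leaf against pericarp 1 of 100 drawn splits reached 4814, the real one, with 676 the highest other. The other splits for time and tissue mix arrays of both real sides, so a real difference goes into the spread or cancels. Their low counts are therefore no measure of chance alone. For the difference of the light effect between leaf and pericarp 7 of 100 reached the real count of 5, up to 11, so chance could give that count.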

How the results depend on the processing

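Of the light effect in leaf at 1 week, 2 probe sets were called, 11 of 16 alternatives moved that count and the cause was not tested. It was 1 with dim probe sets left out, 50 (10 higher, 40 lower) with array weights, 1 with only the groups compared in the fit, 1 with the 3' minus 5' index as a covariate, 1 without both arrays that stand apart, and 0 to 8 when leaving out 1 array. At 2 weeks the count of 0 moved in 1 of 17 alternatives, to 186 without 1000 PPF array A, with 0 to 186 over all single arrays. In pericarp the count of 0 moved in 7 of 16, to 2 with dim probe sets left out, 1 with trend and robust eBayes, 5 (2 higher, 3 lower) with array weights, 583 (250 higher, 333 lower) with all 20 arrays in 1 fit, 18 without both arrays that stand apart, and 0 to 18 when leaving out 1 array.

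For the time effects in leaf, at 200 PPF and 1 week the 2801 became 944 (388 higher, 556 lower) with a fold of at least 2, 4753 with array weights and 371 to 2277 when leaving out 1 array. At 1000 PPF and 1 week the 2632 became 818 (328 higher, 490 lower), 4201 and 1451 to 2398 in the same 3 settings. At 200 PPF and 2 weeks the 4627 became 1811 (748 higher, 1063 lower) with a fold of at least 2, 2206 with the index as a covariate, of which 2118 were among the first, and 3817 to 4507 when leaving out 1 array. At 1000 PPF and 2 weeks the 4791 became 1826 (740 higher, 1086 lower), 2178, of which 2086 were among the first, and 3970 to 4598.

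The change of the light effect between the weeks, 1 probe set, became 0 with dim probe sets left out and 0 to 84 when leaving out 1 array. The difference of the light effect between leaf and pericarp, 5 probe sets, became 1 with dim probe sets left out, 11 with array weights, 53 (25 higher, 28 lower) with all 20 arrays in 1 fit, 0 with the index as a covariate, 16 without both arrays that stand apart, and 1 to 64 when leaving out 1 array. The difference between leaf and pericarp, 4814, became 2163 (1172 higher, 991 lower) with a fold of at least 2 and 4377 to 4974 when leaving out 1 array.

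Of the 12 gene lists called in 80 tests, 0 were called with an estimated correlation, 6 with dim probe sets left out and 2 against a background of the named genes, both between leaf and pericarp, and 9 to 14 when leaving out 1 array; fry called 8, of which 5 were among the 12, all between leaf and pericarp. The correlation of the light effects in leaf at 1 and 2 weeks, -0.128, was -0.200 without both arrays that stand apart and -0.230 to -0.0164 when leaving out 1 array. Between leaf and pericarp it went from -0.190 to -0.0300 with the index as a covariate, and lay at -0.272 to -0.0845 when leaving out 1 array. Of the genes given, only DFR in pericarp changed direction, from -1.37 to 0.36 with the index as a covariate.

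With the replicate letter as a block, 0 probe sets passed for the light effect in leaf at 1 week, 0 for its change between the weeks and 2 for its difference between leaf and pericarp. The block also ended the list calls of the pathogenesis-related genes in leaf at 1 week (adjusted p = 0.0627) and the photosystem genes in pericarp (0.0709), which left 10 of the 12. As a check of pairing, deviations from the group mean were correlated between arrays of the same letter: 0.179, 0.153 and 0.0907 between light levels in leaf at 2 weeks, and -0.0139, 0.0723 and 0.178 in pericarp. Between leaf and pericarp the values for A, B and C were -0.121, -0.0433 and 0.314 at 200 PPF and -0.0619, 0.110 and -0.0366 at 1000 PPF. An array correlated best with its own letter in 5 of 6 cases between light levels in leaf at 2 weeks and 3 of 6 in pericarp. Between leaf and pericarp this held in 2 of 6 at 200 PPF. The hybridisation spike controls averaged 11.41, 11.58 and 11.63 on the C arrays at 2 weeks other than leaf 1000 PPF (9.98), and 9.72 to 10.81 on the A and B arrays of that week, which hints at a shared processing step for 3 of the 4 C arrays only.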

Other observations

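The MADS-box genes AGL11, AG1 and MADS1 had mean values of 11.55, 10.91 and 9.60 log2 in pericarp at 200 PPF and 3.54, 4.73 and 4.68 in leaf at 2 weeks and 200 PPF (n = 3 each). The alcohol dehydrogenase gene ADH2 stood at 13.49 in pericarp at 200 PPF and 7.38 in leaf at 2 weeks and 200 PPF, and at 5.13 in leaf at 1 week and 200 PPF and 4.90 at 0 weeks. Of the gibberellin 20-oxidase genes, 20ox-3 was at 8.09 in pericarp at 200 PPF and 2.91 in leaf at 2 weeks and 200 PPF. At that time 20ox-2 was low in both, 3.24 and 3.61, having been at 8.27 in leaf at 0 weeks, and GA20OX1 was at 10.88 and 8.12, against 11.58 in leaf at 0 weeks.

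The fruit transcript 2A11 stood at 5.63 (SD 1.56) in leaf at 0 weeks and 3.71, 3.38, 3.75 and 4.01 in the later leaf groups, against 14.69 in pericarp at 200 PPF. The chalcone synthase gene CHS2 had a mean of 9.17 with an SD of 4.56 in pericarp at 1000 PPF, and 10.15 (SD 2.36) at 200 PPF, so its arrays disagree where those of CHS1 lie close together (6.05, SD 0.54, and 9.58, SD 0.32). The iron reductase gene FRO1 was near the background in pericarp (2.92 and 3.30 at 200 and 1000 PPF) and at 9.87 in leaf at 0 weeks. The pericarp means of the pectinesterase PME2.1 (7.51 and 9.86, SD 0.34 and 2.61) and the lipoxygenase LOXB (7.67 and 9.35, SD 1.08 and 1.51) are given for 200 and 1000 PPF and did not pass between the light levels.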
